A study of Homo sapiens with 5 samples.

How the data were processed

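Gene expression was measured by bulk RNA sequencing of total RNA from human astrocytes, left to attach and expand after seeding and then treated for 20 h, per the labels' protocols. The labels name 5 samples, 1 for each treatment: the vehicle DMSO, aphidicolin at 10 µM, KH7 at 10 µM, aphidicolin with KH7, and nocodazole at 1 µM. Trimmomatic, STAR, RSEM and limma with the genome build hg38 are named in the submitters' processing notes, and their versions, settings and roles, like the strandedness of the libraries, are not given in the sources used here. Reads of a gene and of an overlapping antisense gene therefore cannot be told apart, and members of gene families with near-identical copies, such as tubulins and ribosomal proteins, are uncertain where reads fit several of them.

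The main table holds, per the file headers, an estimated count per gene for 18 columns: 3 libraries for each treatment, with the DMSO libraries given as 2 lanes each. These expected counts, deposited without normalization, are the unit of all fits made here. The same table gives the authors' log2 fold changes of each treatment against DMSO, the moderated t (a score) of the authors' limma fit, and p-values with the authors' adjusted p-values. The authors' table also gives group averages in FPKM, which were used here only to check how the authors' shorter tables were selected. Each of these shorter deposited tables, 1 per treatment, holds genes with an absolute log2 fold change of at least 0.58, an average of at least 1 FPKM in at least 1 of the groups compared and an adjusted p of at most 0.0417 to 0.0499, and all genes of the main table within these bounds were in them. A refit with limma-voom showed how the authors' fold changes came about: with only DMSO lane 1 as control and only the pair of groups compared, the SD of the difference in log2 was 0.0112 to 0.0147, against 0.109 to 0.11 with lane 2 and 0.0524 to 0.0529 with both lanes.

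The table has 12956 entries and had been filtered before deposit, since the lowest mean count of a gene was 28.7. The 12 genes listed once for each sex chromosome in the pseudoautosomal regions were added up, which left 12944 genes, and the authors' values of the X entry were kept for these. Counts of both lanes were added for each DMSO library. The single columns held 31863515 to 46584418 counts, and transcripts encoded in mitochondria took 1.59% to 2.33% of a library. The mean chi-square per gene was 2.73 to 2.86 between the lanes of a library and 5.7 to 16.4 between libraries of a treatment, so no libraries of a treatment differed as little as lanes did. Between the lanes, edgeR with the library as a block called 13 of 12944 genes.

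The comparisons of each treatment with DMSO use the authors' deposited limma values, with an adjusted p under 0.05 as the threshold and the standard error (SE) as the fold change divided by the moderated t. The comparisons of aphidicolin with KH7 against aphidicolin alone, of KH7 against nocodazole and against aphidicolin, and the interaction (the KH7 effect with aphidicolin minus that without) use edgeR's quasi-likelihood test on the expected counts rounded to whole numbers. One fit over all 5 groups with TMM scaling and no covariate served these, with Benjamini-Hochberg adjustment. The SE is the fold change divided by the square root of edgeR's F statistic. Levels are CPM, a gene's counts scaled to the TMM-adjusted library size. Identifiers and coordinates are those of the authors' files.

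Gene lists fixed before the data were examined numbered 38. They cover phases of the cell cycle, stress and signalling pathways, metabolism, reactive astrocyte states and markers of astrocytes and other cell types, and 36 had at least 5 measured members and were tested. The list tests used the edgeR fit in every comparison: camera with a preset correlation of 0.01 between genes, camera with an estimated correlation, and fry, each adjusted over the lists of a comparison. Fry tests whether the genes of a list move, on balance, one way, and called 30 to 33 of 36 lists in each of the comparisons reported. No list called by camera had a median, mean and test that differed in sign. Counts of members called are given both over all genes and adjusted over the list alone.

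The rule for the genes named was fixed before the data were examined. In each comparison it takes the 10 largest rises and falls among called genes with a mean level at or above the median of 27.6 CPM, and of each list up to 4 called members with the largest change and the 2 measured members with the highest level, called or not. It leaves out unnamed loci, antisense genes, pseudogenes and sex-linked genes. It also takes ADCY10, CDKN1A, MKI67, CCNB1, CCNE2, PCNA, GFAP, VIM, S100B, AQP4, TUBB, LIF, IL6, BDNF and C3 where measured. Only part of these genes is named, and that part, like the genes and lists plotted, was picked with the values in view.

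Alternatives were a stricter adjusted p of 0.01, a log2 change of at least 1, genes or list members at or above the median level, quantile, RLE and library-size scaling, limma-voom, DESeq2, single DMSO lanes, the library number as a block, and leaving out each library in turn. Fold changes against DMSO centred on the median of all genes, and the mean of a list in place of its median, were also taken. No pseudocount was varied, since the fits used counts, and no fit without a filter was possible on a table filtered before deposit. Simulated counts for the 12944 real genes, with 200 of them changed, were used to test the edgeR fit. For KH7 against DMSO it recovered 78.9% of genes changed 1.5-fold, 95.8% of those changed 2-fold and 100% of those changed 4-fold, with 2.63% of calls false. For aphidicolin with KH7 against aphidicolin the shares were 86.6%, 98.5% and 100%, with 5.94% false, and for the interaction 82.1%, 89.5% and 100%, with 4.26% false. The simulations changed 200 genes, against 8468 and 6300 called in the latter comparisons, so these shares need not hold for the real data. The main gene values for KH7 against DMSO are the authors' limma values, not those of this fit. The versions were edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, R 4.3.3 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.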

Results

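The series measured gene expression by bulk RNA sequencing in cultured human astrocytes, the star-shaped glial cells that support neurons. It addressed the role of soluble adenylyl cyclase, an enzyme that makes the second messenger cAMP and is encoded by ADCY10, in the proliferation of these cells. Proliferating cultures were given 1 of 5 treatments for 20 h. They received the vehicle DMSO, 10 µM aphidicolin, 10 µM KH7, both of these compounds together, or 1 µM nocodazole. The label of the sample with both compounds has KH7 given after arrest by aphidicolin, whereas the protocol gives the same incubation for all treatments, so how long each compound was present there is not given in the sources used here. Aphidicolin blocks replicative DNA polymerases, KH7 is an inhibitor of soluble adenylyl cyclase, and nocodazole depolymerises microtubules and holds cells in mitosis. Each treatment is 1 deposited sample, and the count table holds 3 libraries for each, 15 in all. The 12 treated libraries held 33113623 to 46584418 estimated counts. The DMSO libraries, each sequenced in 2 lanes that were added up here, held 65863581 to 76101876. The authors' fold changes against DMSO were matched best by a refit with lane 1 alone as control, whose columns held 34000066 to 39203791. The labels do not say whether the libraries of a treatment came from separate cultures, so every p-value measures the spread between libraries, which may be technical. Levels are CPM, counts scaled to the TMM-adjusted library size, given as the mean and SD of the 3 libraries of a group. Fold changes are on the log2 scale. Gene lists were tested with camera against all other genes, and the adjusted p with an estimated correlation stands beside it where that ended the call. ADCY10, AQP4 and C3 were not among the 12944 genes of the table analysed here.

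Aphidicolin against DMSO shows what this inhibitor of DNA polymerases changed in these astrocytes, in which DNA synthesis was not measured here. Targets of the tumour suppressor p53 rose together: the authors' deposited table had 30 of 30 measured members higher, with a median log2 fold change of 1.13 (the same counts adjusted over the list alone). In the authors' deposited table GDF15, a stress-induced cytokine, had the largest rise among the genes named here, 4.61 (SE 0.115), and CDKN1A, which encodes the cell cycle inhibitor p21, rose by 2.46 (SE 0.0443). The pro-apoptotic gene BBC3 (2.08), the mitochondrial reductase gene FDXR (2.04) and the p53 ubiquitin ligase gene MDM2 (1.44) rose in the authors' deposited table as well. GDF15 (identifier ENSG00000130513.6) lies on chromosome 19 at 18386158 to 18389176 and CDKN1A (ENSG00000124762.13) on chromosome 6 at 36678658 to 36687339 (hg38, as in the authors' files). GDF15 went from 5.01 ± 1.09 CPM with DMSO to 132 ± 18.4 CPM with aphidicolin (SD, n = 3 each), and CDKN1A from 266 ± 3.61 to 1495 ± 57.8 CPM (SD, n = 3 each). Among other large rises in the authors' deposited table were the transcription factor ATF3 (2.76), EPS8L2 (2.62), FAM212B (2.41), the decoy receptor TNFRSF10C (2.4), EPPK1 (2.23) and the lipoprotein lipase inhibitor ANGPTL4 (2.22). The p53 targets as a list had adjusted p = 7.72e-92 by camera.

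Genes of mitosis fell with aphidicolin while genes of DNA replication went both ways. The authors' deposited table had 47 of 50 measured genes of G2 and mitosis lower and 1 higher (1 higher and 48 lower adjusted over the list alone). The falls were led, in the authors' deposited table, by the mitotic kinase gene PLK1 (-2.09, SE 0.0676), the kinesin KIF20A (-2.03), the anaphase activator CDC20 (-1.98), DLGAP5 (-1.72) and cyclin B1, CCNB1 (-1.52, SE 0.0518). HMMR (-1.49), DEPDC1 (-1.48), AURKA (-1.48), ASPM (-1.32), CCNB2 (-1.32) and TOP2A (-0.68) were lower in the authors' deposited table too. Of 46 genes of DNA replication and S phase, 24 were higher and 9 lower in the authors' deposited table (27 higher and 9 lower adjusted over the list alone). Of these the licensing factor CDT1 (0.81), thymidylate synthase TYMS (0.8), CCNE2 (0.75) and PCNA (0.53) rose in the authors' deposited table, and the helicase subunits MCM6 (-0.8) and MCM7 (-0.41) fell. MKI67, the proliferation marker Ki-67, did not pass the test in the authors' deposited table (-0.21, adjusted p = 0.0597). The mitotic list had adjusted p = 8.43e-67 by camera, and the S phase list adjusted p = 0.000713 and adjusted p = 0.271 with an estimated correlation.

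ATF4 targets of the integrated stress response, 21 of 30 measured, were higher with aphidicolin in the authors' deposited table, among them DDIT3 (1.63) and SESN2 (1.49), and 2 were lower (the same counts adjusted over the list alone). ATF4 targets had adjusted p = 3.51e-13 by camera. Of 28 genes of trophic factors, 11 rose and 2 fell in the authors' deposited table (the same counts adjusted over the list alone), and the rises included IL11 (1.29) and LIF (1.26, SE 0.065). Trophic factor genes had adjusted p = 3.71e-06 by camera, and IL11, LIF and IL6 also stand in the list of NF-kB targets. IL6 and BDNF did not pass the test in the authors' deposited table (0.04 and -0.19), and IL6 was at -0.04 with quantile scaling. Interferon response genes were higher for 10 of 21 members and lower for 2 in the authors' deposited table, with OAS3 (1.02) and ISG15 (0.84) among them (the same counts adjusted over the list alone). Interferon response genes had adjusted p = 0.00383 by camera, and with only the members at or above the median level adjusted p = 0.597 and a median log2 of 0.03. Cytosolic ribosomal protein genes were lower for 40 of 42 members in the authors' deposited table, with a median log2 of -0.23 (the same counts adjusted over the list alone). That list had adjusted p = 1e-05 by camera and adjusted p = 0.543 with an estimated correlation. The astrocyte identity list had 8 genes higher and 7 lower of 20 in the authors' deposited table, with HEPACAM at 1.78, GFAP at -0.26 and S100B at 0.33 (the same counts adjusted over the list alone). Astrocyte identity genes had adjusted p = 0.395 by camera. VIM (-0.54) and TUBB (-0.37) fell in the authors' deposited table. In the edgeR fit of the summed lanes S100B did not pass (0.21, adjusted p = 0.101), whereas BDNF (-0.19, adjusted p = 0.0163) and MKI67 (-0.19, adjusted p = 0.0454) did. In all, 5414 of 12944 genes had an adjusted p under 0.05 in the authors' deposited table, 2723 higher and 2691 lower. A log2 change of at least 1 was seen for 246 of the higher and 71 of the lower genes in the authors' deposited table. Of the calls with scaling to library size only, 58.3 percent were higher, against 50.3 percent with the authors' deposited table.

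**Figure D1:**
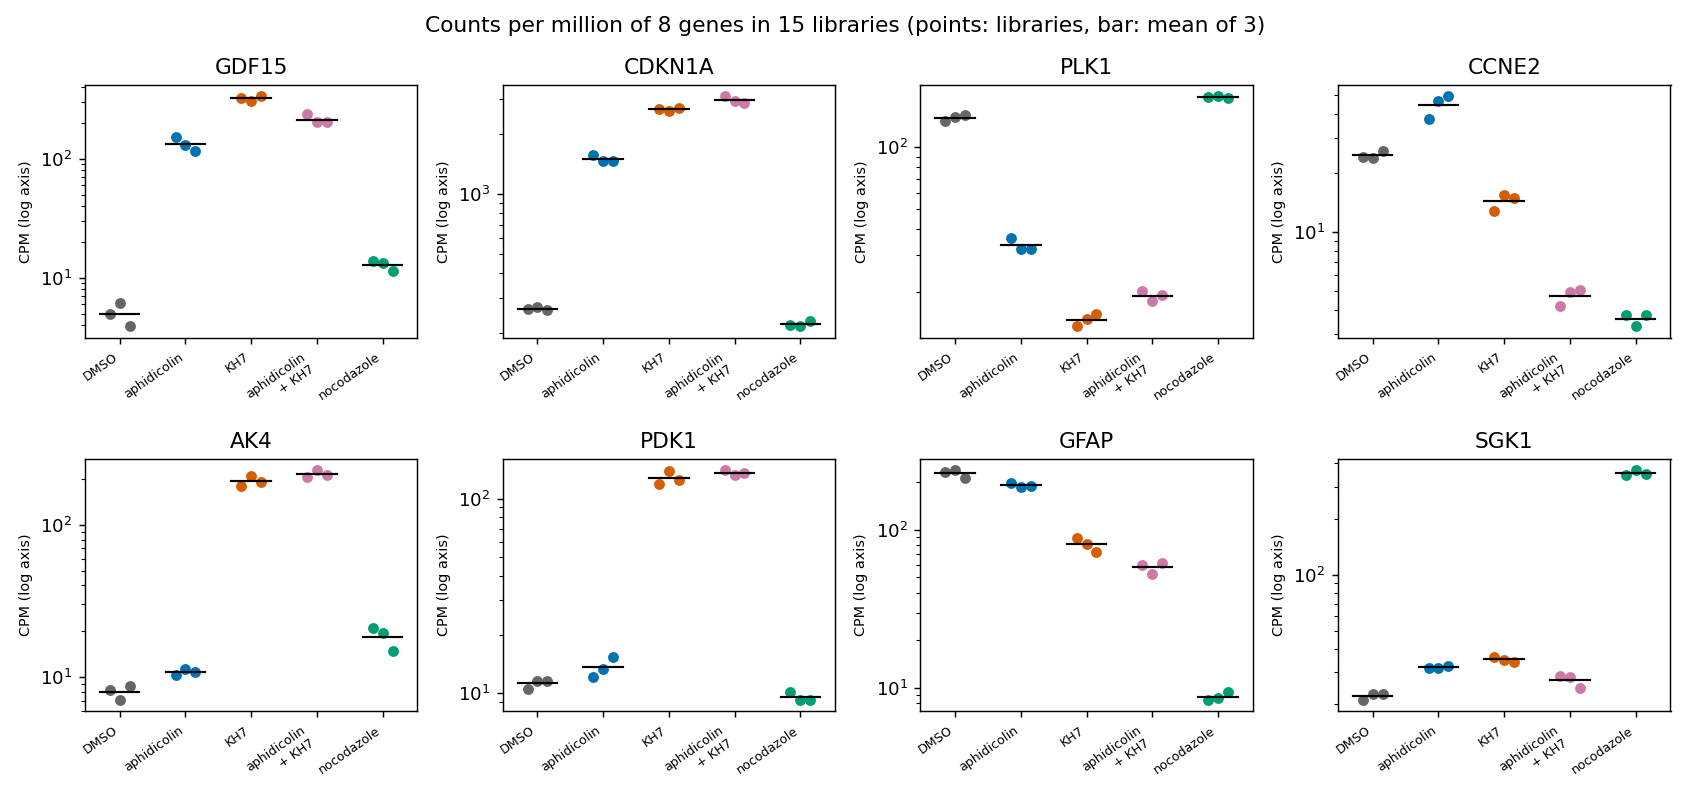
CPM (counts scaled to the TMM-adjusted library size) on a log axis for 8 genes in each of the 15 libraries by treatment. Points are libraries and a bar is the mean of 3. GDF15 and CDKN1A are higher in the libraries with aphidicolin, KH7 or both than with DMSO, AK4 and PDK1 are highest in the libraries given KH7 with or without aphidicolin, and GFAP is lowest with nocodazole.

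KH7 against DMSO asks what KH7, an inhibitor of soluble adenylyl cyclase, did on its own. Targets of the hypoxia-inducible factor HIF and genes of glycolysis rose strongly. All 18 measured HIF targets were higher in the authors' deposited table, with a median log2 fold change of 2.21 (the same counts adjusted over the list alone), led by ANGPTL4 (4.02, SE 0.0661), the pyruvate dehydrogenase kinase PDK1 (3.51, SE 0.0735), NDRG1 (3.48) and the collagen prolyl hydroxylase subunit P4HA1 (3.21). Of 24 glycolysis genes, 22 were higher and 2 lower in the authors' deposited table (the same counts adjusted over the list alone), including the aldolase ALDOC (3.7), PGK1 (2.58), ENO2 (2.31) and GAPDH (0.95). PDK1 and SLC2A1 stand in both lists. AK4, a mitochondrial adenylate kinase (ENSG00000162433.14) on chromosome 1 at 65148203 to 65232136, had a log2 fold change of 4.60 (SE 0.0929) in the authors' deposited table. Its level was 8.01 ± 0.833 CPM with DMSO and 193 ± 14.6 CPM with KH7 (SD, n = 3 each). HIF targets had adjusted p = 5.21e-55 by camera and glycolysis genes adjusted p = 9e-35.

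Targets of ATF4 and of p53 rose with KH7. All 30 measured ATF4 targets were higher in the authors' deposited table, by a median of 2.15 (the same counts adjusted over the list alone), among them ATF3 (4.75, SE 0.0963), the pseudokinase TRIB3 (4.15), DDIT3 (3.98), CHAC1 (3.74) and the amino acid transporter SLC7A5 (2.71). All 30 p53 targets were higher as well in the authors' deposited table, by a median of 1.79 (the same counts adjusted over the list alone), with GDF15 at 5.91 (SE 0.119), CDKN1A at 3.30 (SE 0.0347), SESN2 at 3.4 and MDM2 at 2.59. GDF15 reached 321 ± 14.6 CPM and CDKN1A 2651 ± 55.9 CPM (SD, n = 3 each). SESN2 stands in both lists. DDIT4 (3.58), a stress-induced inhibitor of mTORC1 signalling, and IGFBP3 (3.44), a binding protein of insulin-like growth factors, were among the largest rises in the authors' deposited table. Sterol biosynthesis genes rose for 23 of 25 members and fell for 0 in the authors' deposited table (24 higher and 0 lower adjusted over the list alone), with HMGCS1 at 1.43 and DHCR7 at 1.28 among them. ATF4 targets had adjusted p = 9.55e-91 by camera, p53 targets adjusted p = 6.44e-75 and sterol genes adjusted p = 1.21e-13.

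The cell cycle genes fell with KH7. All 50 measured genes of G2 and mitosis were lower in the authors' deposited table, with a median log2 fold change of -1.62 (the same counts adjusted over the list alone). Among the largest falls in the authors' deposited table were PLK1 at -3.27 (SE 0.0661), KIF20A at -3.15, CDC20 at -3.07, DLGAP5 at -2.97, CCNB1 at -2.77 (SE 0.0541), ASPM at -2.62, AURKA at -2.45, DEPDC1 at -2.42, BUB1 at -2.3, CCNB2 at -2.18 and MKI67 at -1.07. PLK1 (ENSG00000166851.14), on chromosome 16 at 23678822 to 23690367, went from 139 ± 4.17 CPM with DMSO to 14.6 ± 0.963 CPM with KH7 (SD, n = 3 each). Of the 46 S phase genes 40 were lower and 1 higher in the authors' deposited table, the largest falls being those of POLE2 (-1.69) and UHRF1 (-1.67), while PCNA was at 0.17 and CCNE2 at -0.87 (the same counts adjusted over the list alone). Mitotic genes had adjusted p = 4.19e-95 by camera and S phase genes adjusted p = 5.59e-11.

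Genes that answer to cAMP through the transcription factor CREB went up more often than down with KH7. In the authors' deposited table, 17 of 25 were higher and 2 lower (18 higher and 2 lower adjusted over the list alone), the largest being ATF3 as above, MAFF (1.55), the orphan receptor NR4A1 (1.38) and EGR1 (1.2), which also answer to stress and growth factors. Of 29 genes of cyclases, phosphodiesterases and cAMP effectors, 10 were higher and 10 lower in the authors' deposited table, ADCY1 at 1.22 and PDE3B at -1.05 among them (the same counts adjusted over the list alone). CREB targets had adjusted p = 2.33e-05 by camera and genes of cAMP metabolism adjusted p = 0.635. The lists of reactive astrocyte genes were not called: a pan-reactive list and the A1 and A2 lists, which are reactive states described in mice. In the authors' deposited table the pan-reactive list had 5 higher and 3 lower of 8, the A1 list 3 and 5, and the A2 list 3 and 3 (the same counts adjusted over the list alone for each). Pan-reactive genes had adjusted p = 0.245 by camera, A1 genes adjusted p = 0.309 and A2 genes adjusted p = 0.599. GFAP, the astrocyte intermediate filament gene, was at -1.49 (SE 0.0483), SERPINA3 at 1.41, S100B at -0.97 and VIM at -0.12 in the authors' deposited table. Astrocyte identity genes were higher for 7 and lower for 9 of 20 in the authors' deposited table (the same counts adjusted over the list alone). Astrocyte identity genes had adjusted p = 0.952 by camera.

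Trophic factor genes rose for 13 of 28 and fell for 9 with KH7 in the authors' deposited table, among them VEGFA (2.51), HBEGF (1.95), LIF (1.89, SE 0.0585) and BDNF (0.4), while IL6 at 0.19 did not pass (the same counts adjusted over the list alone). VEGFA also stands in the list of HIF targets, and LIF and IL6 in that of NF-kB targets. Targets of NF-kB had 9 of 16 higher and 3 lower in the authors' deposited table (the same counts adjusted over the list alone), with TNFAIP3 (3.37) and BIRC3 (3.06) first. Cytoskeleton targets of the factors SRF and MRTF were lower for 21 of 26 and higher for 4 in the authors' deposited table, with LMOD1 (-1.96), CNN1 (-1.85) and ACTB (-0.72) lower (the same counts adjusted over the list alone). Trophic factor genes had adjusted p = 8.48e-05 by camera, NF-kB targets adjusted p = 3.06e-06 and SRF and MRTF targets adjusted p = 2.33e-05. Of 10 neuronal markers, 4 rose and 3 fell in the authors' deposited table (the same counts adjusted over the list alone), and the rises were ENO2, which is also a glycolysis gene, the filament genes INA (1.57) and NEFL (1.21), and SYT1 (1.25). Neuronal markers had adjusted p = 0.000489 by camera. Tubulin genes, whose reads partly fit several family members, were lower for 11 of 14 and higher for 2 in the authors' deposited table, TUBB at -1.03 and TUBA1B at -1.26 (the same counts adjusted over the list alone). Tubulin genes had adjusted p = 0.00011 by camera and adjusted p = 0.134 with an estimated correlation. Altogether 8496 genes had an adjusted p under 0.05 in the authors' deposited table, 4203 higher and 4293 lower, and 609 and 432 of them moved by a log2 of at least 1. Higher genes made up 43.9 percent of the calls with scaling to library size only, against 49.5 percent with the authors' deposited table. The VIM call was lost in edgeR without DMSO replicate 1 (adjusted p = 0.0522) and without KH7 replicate 1 (adjusted p = 0.0753), and with quantile scaling, where VIM was at 0. IL6 passed in edgeR without DMSO replicate 1 (0.41, adjusted p = 0.0242).

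**Figure D2:**
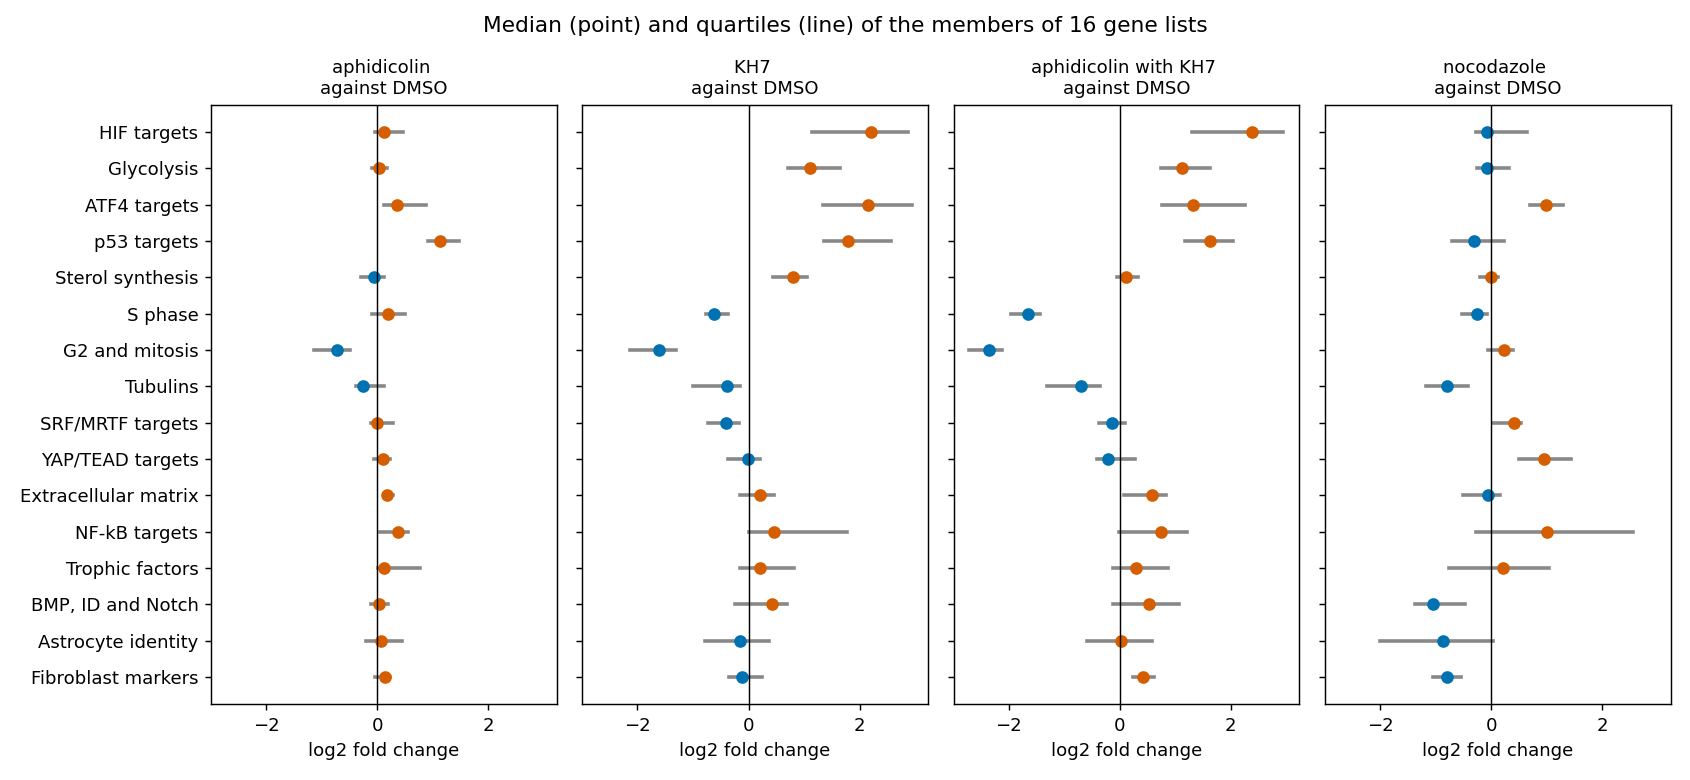
Median log2 fold change against DMSO of 16 gene lists, from the authors' deposited table, for the 4 treatments, with points for the median over the measured members and lines between the quartiles. HIF targets, glycolysis, ATF4 targets and p53 targets lie to the right of 0 with KH7 and with both compounds, and astrocyte identity genes lie to the left with nocodazole.

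Aphidicolin with KH7 against DMSO shows the cells given both compounds. HIF targets and glycolysis genes rose: all 18 HIF targets were higher in the authors' deposited table with a median of 2.38 (the same counts adjusted over the list alone), and 22 of 24 glycolysis genes were higher and 2 lower (the same counts adjusted over the list alone). AK4 (4.73, SE 0.0978), ANGPTL4 (4.26), PDK1 (3.59), P4HA1 (3.57), IGFBP3 (3.51), the HIF subunit gene EPAS1 (3.56) and the retinol dehydrogenase RDH10 (3.4) were among the largest rises in the authors' deposited table. GDF15 (5.29, SE 0.12), ATF3 (3.46) and CDKN1A (3.43, SE 0.0459) rose there too in the authors' deposited table, where 29 of 30 p53 targets (the same counts adjusted over the list alone) and 29 of 30 ATF4 targets (the same counts adjusted over the list alone) were higher. HIF targets had adjusted p = 4.33e-51 by camera, glycolysis genes adjusted p = 3.04e-32, p53 targets adjusted p = 6.46e-51 and ATF4 targets adjusted p = 1.64e-37. Sterol genes were higher for 10 and lower for 5 of 25 in the authors' deposited table (the same counts adjusted over the list alone), with ACAT2 at -1.12 and FDPS at -0.84. Their median of 0.10 turned to -0.06 with scaling to library size only, and they had adjusted p = 0.882 by camera.

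The fall of cell cycle genes covered both phases with the compounds together. All 50 genes of G2 and mitosis were lower in the authors' deposited table with a median of -2.36 (the same counts adjusted over the list alone), and 45 of 46 S phase genes were lower with a median of -1.66 (the same counts adjusted over the list alone). Among the largest falls of mitotic genes in the authors' deposited table were DLGAP5 (-3.12), KIF20A (-3.11), ASPM (-3.04), AURKB (-2.99), PLK1 (-2.90, SE 0.0717), CENPE (-2.88), KIF23 (-2.82), CDC20 (-2.81), CDCA8 (-2.79) and NDC80 (-2.76). E2F2 (-2.78), CCNE2 (-2.48, SE 0.121), CCNB1 (-2.64) and MKI67 (-2.41) fell as well in the authors' deposited table, and PCNA did not pass (-0.04). Mitotic genes had adjusted p = 4.82e-129 by camera and S phase genes adjusted p = 9.34e-53. Extracellular matrix genes were higher for 21 of 29 and lower for 2 in the authors' deposited table, with LOXL2 (1.77), LOX (1.71) and fibronectin FN1 (0.85) higher (the same counts adjusted over the list alone). LOX also stands in the list of HIF targets. Fibroblast and meningeal markers were higher for 10 of 14 and lower for 1 in the authors' deposited table, FOXC1 at 2.05 and COL1A1 at 0.56 (the same counts adjusted over the list alone). Matrix genes had adjusted p = 4.23e-09 by camera and fibroblast markers adjusted p = 0.00641 and adjusted p = 0.135 with an estimated correlation. GFAP was at -1.99 (SE 0.0656), S100B at -0.41, VIM at 0.13, TUBB at -1.41, LIF at 1.05 and BDNF at 0.22 in the authors' deposited table, and IL6 at 0.45 did not pass there but did in the edgeR fit (0.50, adjusted p = 0.00473). With quantile scaling COL1A1 was at -0.049 and VIM at 0, neither past the test, and PCNA passed (-0.12, adjusted p = 0.0122). Library-size scaling put VIM at -0.002 and BDNF at 0.08, neither past the test, and PCNA passed there too. In the authors' deposited table, 8194 genes were called, 3997 higher and 4197 lower, with 541 and 751 at a log2 of at least 1. With scaling to library size only, the median of all genes lay at -0.15, and 34 percent of the calls were higher against 48.8 percent with the authors' deposited table.

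Nocodazole against DMSO shows cells given a compound that depolymerises microtubules, whose state was not measured here. Genes of astrocyte identity fell: in the authors' deposited table, 13 of 20 measured members were lower and 5 higher, with a median log2 of -0.87 (5 higher and 14 lower adjusted over the list alone). GFAP had a log2 fold change of -4.69 (SE 0.0779) in the authors' deposited table, the glutamate transporter SLC1A3 -2.64, NDRG2 -2.28, the integrin ITGB4 -3.33 and S100B -2.02, while the gap junction gene GJA1 was at 0.1. GJA1 did not pass in the edgeR fit (0.09, adjusted p = 0.0639) and was at -0.001 with library-size scaling. GFAP (ENSG00000131095.12), on chromosome 17 at 44905645 to 44915500, went from 227 ± 12.5 CPM with DMSO to 8.84 ± 0.538 CPM with nocodazole (SD, n = 3 each). Other large falls in the authors' deposited table were the substance P receptor TACR1 (-4.7), LRRN3 (-4.56), the transcription factor SOX21 (-4.33), MXRA5 (-4.14), the granin SCG2 (-3.92), the engulfment receptor MEGF10 (-3.7), STK32A (-3.61) and SLC2A12 (-3.5). Lists of other cell types fell beside them in the authors' deposited table: 6 of 6 oligodendrocyte lineage markers (the same counts adjusted over the list alone), 13 of 14 fibroblast markers with 1 higher (the same counts adjusted over the list alone), and 10 of 12 neural progenitor markers with 1 higher (the same counts adjusted over the list alone). OLIG1 (-3.69), PDGFRB (-2.09) and FABP7 (-3.14) led these falls in the authors' deposited table. Astrocyte identity genes had adjusted p = 5.72e-08 by camera, oligodendrocyte markers adjusted p = 2.49e-06, fibroblast markers adjusted p = 3.41e-07 and progenitor markers adjusted p = 4.52e-08. Neuronal markers had 4 higher and 5 lower of 10 in the authors' deposited table, with NEFM at -2.76 (the same counts adjusted over the list alone), and endothelial and mural markers 1 and 6 of 9 (the same counts adjusted over the list alone). Neuronal markers had adjusted p = 0.0121 by camera and adjusted p = 0.082 with an estimated correlation and endothelial and mural markers adjusted p = 0.0815. With only the members at or above the median level, neuronal markers had adjusted p = 0.464 and a median of 0.66. Only 2 microglia markers were measured, too few to test.

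Targets of the mechanosensitive factors YAP and TEAD rose with nocodazole: 16 of 19 were higher and 2 lower in the authors' deposited table (the same counts adjusted over the list alone), among them WWC1 (2.44), tissue factor F3 (2.0), ANKRD1 (1.7) and CYR61 (1.64). SRF and MRTF targets were higher for 17 of 26 and lower for 5 in the authors' deposited table, with FLNC at 1.97 and TAGLN at 1.16 (the same counts adjusted over the list alone). Among the largest rises in the authors' deposited table were the kinase gene SGK1 (4.02, SE 0.0547), IGFBP5 (3.24), the cytokine IL11 (2.89), the phosphatase DUSP1 (2.88), RND3 (2.6), NABP1 (2.48), the immune checkpoint ligand CD274 (2.47), CITED2 (2.47) and SLC7A5 (2.35). ATF4 targets were higher for 28 of 30 and lower for 2 in the authors' deposited table (the same counts adjusted over the list alone), and NF-kB targets for 10 of 16, with 4 lower (the same counts adjusted over the list alone). Of the BMP, ID and Notch pathway genes 14 of 19 were lower and 1 higher in the authors' deposited table, BMP2 (-2.59), HEY1 (-2.12) and ID2 (-2.12) first (the same counts adjusted over the list alone). YAP and TEAD targets had adjusted p = 5.95e-18 by camera, SRF and MRTF targets adjusted p = 0.000335 and adjusted p = 0.1 with an estimated correlation, ATF4 targets adjusted p = 2.16e-18, NF-kB targets adjusted p = 0.000161 and adjusted p = 0.0842 with an estimated correlation and BMP, ID and Notch genes adjusted p = 1.39e-06 and adjusted p = 0.0732 with an estimated correlation.

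Mitotic genes were mostly somewhat higher with nocodazole, 30 of 50 in the authors' deposited table against 11 lower, with CENPE at 1.03, CCNB1 at 0.26 (SE 0.0405) and MKI67 at 0.38 (the same counts adjusted over the list alone). S phase genes were lower for 32 of 46 and higher for 6 in the authors' deposited table, CCNE2 at -2.85 (SE 0.112) and PCNA at -0.8 (the same counts adjusted over the list alone). Mitotic genes had adjusted p = 0.032 by camera and adjusted p = 0.557 with an estimated correlation and S phase genes adjusted p = 0.000967 and adjusted p = 0.252 with an estimated correlation. p53 targets had 9 higher and 19 lower of 30 in the authors' deposited table, BTG2 at -1.53, CDKN1A at -0.28 and GDF15 at 1.26 (the same counts adjusted over the list alone). As a list they had adjusted p = 0.286 by camera. Tubulin genes were lower for 12 of 14 and higher for 1 in the authors' deposited table, with TUBB at -1.52 (SE 0.0315) and TUBA1A at -1.36 (the same counts adjusted over the list alone). Tubulin genes had adjusted p = 1.33e-07 by camera and adjusted p = 0.0732 with an estimated correlation. HIF targets went both ways in the authors' deposited table, 8 higher and 8 lower of 18 (the same counts adjusted over the list alone), and as a list had adjusted p = 0.286 by camera. LIF (1.51) and BDNF (1.32) rose, VIM (-0.39) fell and IL6 did not pass (0.23) in the authors' deposited table. The authors' deposited table called 8669 genes, 4340 higher and 4329 lower, 500 and 853 of them by a log2 of at least 1. With scaling to library size only, the median of all genes lay at -0.10, and 38.6 percent of the calls were higher against 50.1 percent with the authors' deposited table. IL6 passed in edgeR without DMSO replicate 1 (0.46, adjusted p = 0.0126) and with quantile scaling (0.50, adjusted p = 0.0037).

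Aphidicolin with KH7 against aphidicolin alone asks what KH7 changed in cells also given aphidicolin, and was tested with edgeR's quasi-likelihood test. HIF targets rose for all 18 members, by a median log2 of 1.98 (the same counts adjusted over the list alone), and glycolysis genes for 22 of 24, with 2 lower (the same counts adjusted over the list alone). AK4 rose by 4.31 (SE 0.0923), P4HA1 by 3.62, the transferrin receptor TFRC by 3.34 (SE 0.05), PDK1 by 3.31, IGFBP3 by 3.27, FAM162A by 3.09, ALDOC by 3.02, STC2 by 2.92, the mitophagy receptor BNIP3 by 2.83 and PGK1 by 2.8. All 46 S phase genes fell, with a median of -1.84 (the same counts adjusted over the list alone), as did all 50 genes of G2 and mitosis (the same counts adjusted over the list alone). Genes with large falls included FAM111A (-2.99), CLSPN (-2.77), the licensing factor CDC6 (-2.72), ESCO2 (-2.69), TCF19 (-2.69), BRIP1 (-2.61), ZWINT (-2.6), ASF1B (-2.6), RRM2 (-2.57) and DTL (-2.51). CCNE2 was 44.2 ± 6.08 CPM with aphidicolin and 4.71 ± 0.452 CPM with both (SD, n = 3 each), a log2 fold change of -3.23 (SE 0.106) with edgeR's adjusted p = 7.44e-19. ATF4 targets rose for 29 of 30 (29 higher and 1 lower adjusted over the list alone) and p53 targets for 23 of 30 with 2 lower (24 higher and 2 lower adjusted over the list alone), CDKN1A by 0.98 (SE 0.0423). HIF targets had adjusted p = 2.5e-52 by camera, glycolysis genes adjusted p = 1.16e-39, S phase genes adjusted p = 1.01e-85, mitotic genes adjusted p = 7.78e-70, ATF4 targets adjusted p = 1.05e-23 and p53 targets adjusted p = 1.97e-06. All 42 ribosomal protein genes were higher, by a median of 0.34 (the same counts adjusted over the list alone). That list had adjusted p = 3.51e-06 by camera and adjusted p = 0.479 with an estimated correlation. GFAP (-1.72), S100B (-0.73), MKI67 (-2.19), CCNB1 (-1.12), PCNA (-0.57), TUBB (-1.04) and LIF (-0.21) were lower, and VIM (0.67), BDNF (0.42) and IL6 (0.44) higher. By edgeR 8468 genes were called, 4254 higher and 4214 lower, with 307 and 803 at a log2 of at least 1. Scaling to library size only put the median of all genes at -0.17 and gave 28.6 percent of the calls as higher, against 50.2 percent. The IL6 call was lost without replicate 3 of the libraries with both compounds (0.30, adjusted p = 0.126) and with library-size scaling (0.26, adjusted p = 0.143).

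The difference between the KH7 effect with and without aphidicolin was tested as an interaction in the same edgeR fit. The KH7 effect on p53 targets was smaller with aphidicolin for 30 of 30 genes, with a median difference of -1.30 (the same counts adjusted over the list alone). GDF15 differed by -5.32 (SE 0.143), ATF3 by -4.09 (SE 0.12), FAM212B by -2.83, FDXR by -2.56, EPS8L2 by -2.52, the caspase adaptor PIDD1 by -2.47, BBC3 by -2.41 and CDKN1A by -2.34 (SE 0.0602). For GDF15 the level was 321 ± 14.6 CPM with KH7 and 213 ± 19.9 CPM with both compounds (SD, n = 3 each). ATF4 targets had 28 of 30 below 0 and 1 above (the same counts adjusted over the list alone), sterol genes 24 of 25 below 0 and 0 above (the same counts adjusted over the list alone). S phase genes fell more with KH7 when aphidicolin was present, 43 of 46 with a median difference of -1.29 (the same counts adjusted over the list alone), among them CDC6 (-2.65, SE 0.0733), DTL (-2.6), TCF19 (-2.51) and CCNE2 (-2.45). Mitotic genes went both ways, 22 of 50 above and 17 below 0 with a median of 0.14 (22 higher and 18 lower adjusted over the list alone), and had adjusted p = 0.00333 by camera and adjusted p = 0.538 with an estimated correlation. MYBL2 (-1.91) and MKI67 (-1.12) were among the negative and PLK1 2.44 (SE 0.0867), CDC20 2.24, KIF20A 2.07, CCNB1 1.68, DLGAP5 1.57, HMMR 1.5, AURKA 1.38 and DEPDC1 1.34 among the positive differences. NRXN3 (1.92) and TACR1 (1.55) were positive as well. HIF targets had 2 genes above and 6 below 0 of 18, with a median of 0.00, which was -0.13 with scaling to library size only, and quartiles of -0.22 and 0.16 (the same counts adjusted over the list alone). The p53 targets had adjusted p = 1.33e-66 by camera, ATF4 targets adjusted p = 5.33e-40, sterol genes adjusted p = 3.64e-13, S phase genes adjusted p = 1.64e-54 and HIF targets adjusted p = 0.361. By edgeR 6300 genes differed, 2997 above and 3303 below 0, with 139 and 735 at a log2 of at least 1. Scaling to library size only put the median of all genes at -0.14 and gave 27 percent of the calls as above 0, against 47.6 percent. Of 312 genes that edgeR called with a log2 change of at least 1 by aphidicolin alone, 36.2% moved the same way between KH7 and both compounds, and an exchange of labels between these groups was not excluded.

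**Figure D3:**
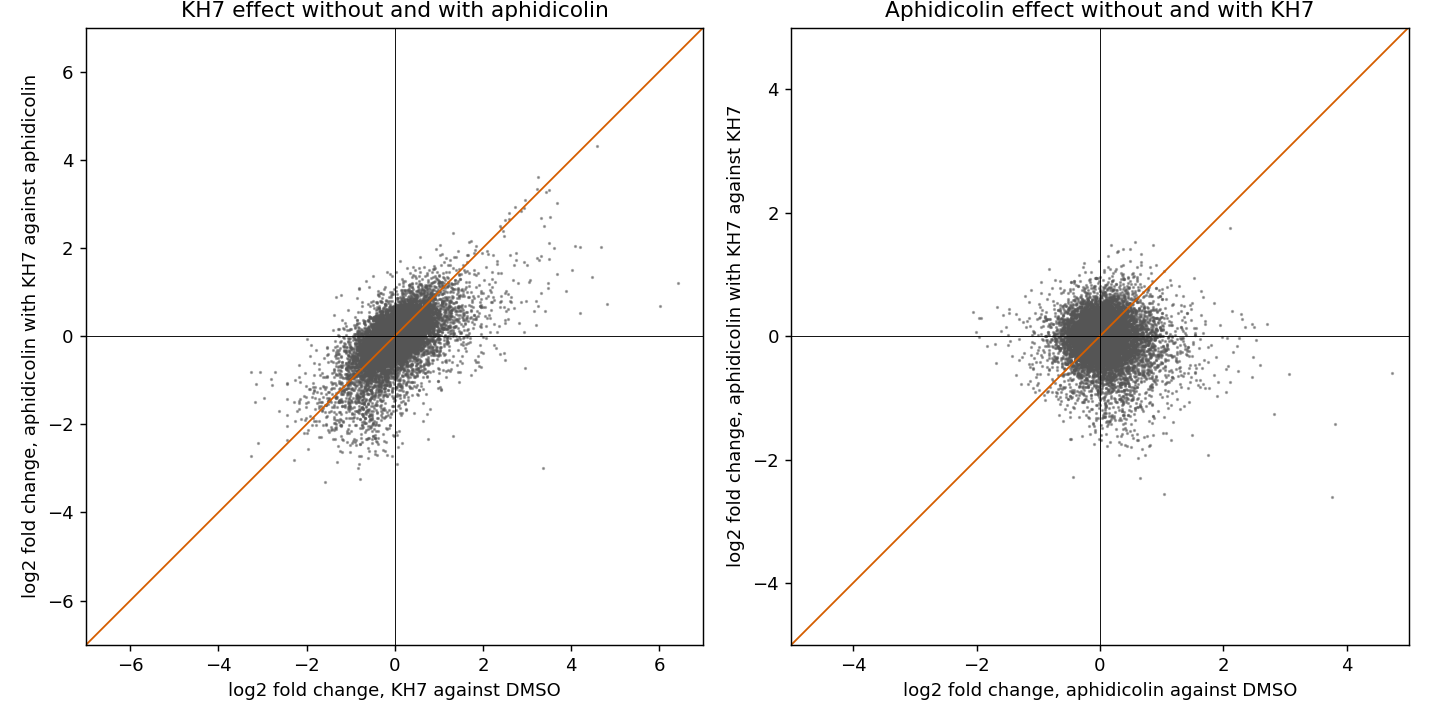
Fold changes across genes from edgeR, each point 1 of 12933 genes, on log2 axes with a line of equal effects. On the left the KH7 effect with aphidicolin is plotted against that without (r = 0.59), and on the right the aphidicolin effect in the presence of KH7 is plotted against that without KH7 (r = -0.08).

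KH7 against nocodazole and against aphidicolin sets the cyclase inhibitor beside compounds that the labels give as synchronising proliferating astrocytes. Arrest itself was not measured here for any of them. Against nocodazole, astrocyte identity genes were higher with KH7 for 16 of 20 and lower for 1 (the same counts adjusted over the list alone), with GFAP at 3.20 (SE 0.0808). ALDOC (4.77), GDF15 (4.63), FDXR (4.52), FAM212B (4.49), SCG2 (4.28), SOX21 (4.02), NDRG1 (3.95), TRIM9 (3.94), MXRA5 (3.87) and RGS16 (3.82) were among the most raised with KH7. All 50 genes of G2 and mitosis were lower with KH7 (the same counts adjusted over the list alone), and PLK1 (-3.58), CDC20 (-3.36), SGK1 (-3.35), the transglutaminase TGM2 (-3.22) and CENPE (-3.13) among the most lowered. YAP and TEAD targets were lower with KH7 for 15 of 19 and higher for 4 (the same counts adjusted over the list alone). Astrocyte identity genes had adjusted p = 4.68e-06 by camera, mitotic genes adjusted p = 6.78e-70 and YAP and TEAD targets adjusted p = 1.75e-09. Against aphidicolin, all 18 HIF targets (the same counts adjusted over the list alone), all 30 ATF4 targets (the same counts adjusted over the list alone) and 22 of 25 sterol genes (the same counts adjusted over the list alone) were higher with KH7. AK4 (4.15, SE 0.092), TFRC (3.56), ALDOC (3.53), P4HA1 (3.24) and PDK1 (3.22) were among the most raised, and the contractile gene CNN1 (-2.61, SE 0.0735), TGM2 (-2.04), GALNT5 (-1.92), PRTFDC1 (-1.85) and the keratin KRT8 (-1.85) among the genes lower with KH7. All 46 S phase genes were lower with KH7 than with aphidicolin, with a median of -0.78 (the same counts adjusted over the list alone). SRF and MRTF targets were lower with KH7 for 20 of 26 and higher for 2 (the same counts adjusted over the list alone). HIF targets had adjusted p = 9.8e-61 by camera, ATF4 targets adjusted p = 3.56e-84, sterol genes adjusted p = 1.63e-23, S phase genes adjusted p = 1.25e-26 and SRF and MRTF targets adjusted p = 2.13e-09. By edgeR 9614 genes differed between KH7 and nocodazole, 4856 of them higher with KH7, and 8085 between KH7 and aphidicolin, 4014 of them higher with KH7. With scaling to library size only, 54.8 and 39.7 percent of the calls were higher with KH7 in that order, against 50.5 and 49.6 percent.

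The calls of the comparisons against DMSO overlapped, and all of these share the DMSO libraries. Between KH7 and both compounds, 3062 genes were higher in both and 3265 lower in both in the authors' deposited table, against 1298 and 1392 for independent lists of those sizes, and 218 were called in opposite directions. Between KH7 and aphidicolin the authors' deposited table shared 1577 higher and 1703 lower genes, against 884 and 892, and 849 genes were called in opposite directions. Between KH7 and nocodazole the authors' deposited table shared 1770 and 1820, against 1409 and 1436, with 2414 opposite. Aphidicolin shared 1516 higher and 1600 lower genes with both compounds in the authors' deposited table (841 and 872 if independent, 892 opposite) and 1159 and 1058 with nocodazole (913 and 900, 1738 opposite). Both compounds shared 1535 and 1506 with nocodazole in the authors' deposited table (1340.2 and 1404, 2708 opposite). Unchanged groups that shared a DMSO control were simulated 20 times. EdgeR gave a mean of 0.05 shared calls, a correlation of fold changes of 0.5 and a covariance of 0.00589. With no gene changed, adjustment leaves few calls, and a shared control alone fixes a correlation near 0.5. These shared calls and this correlation are therefore no yardstick for treatments that changed many genes. The overlaps above also rest on the authors' limma calls, not on edgeR. The observed correlation across genes, which are not independent replicates, was taken from the edgeR fit with both DMSO lanes added, not from the deposited values. It was 0.84 (covariance 0.335) for KH7 and both compounds, 0.53 (covariance 0.121) for aphidicolin and KH7 and 0.21 (covariance 0.0868) for KH7 and nocodazole. It was 0.45 (covariance 0.111) for aphidicolin and both compounds, 0.13 (covariance 0.0337) for aphidicolin and nocodazole and 0.08 (covariance 0.035) for both compounds and nocodazole. The DMSO libraries were not split between the comparisons, so part of each excess may come from them. In comparisons that share no library, also in edgeR, the KH7 effects without and with aphidicolin correlated at r = 0.59 across genes (Spearman's rho 0.58). There 2630 genes were called higher in both and 2703 lower in both, against 1407 and 1420.4 for independent lists. The aphidicolin effects without and with KH7 correlated at r = -0.08 across genes (rho -0.03).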

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

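Of the tests in this part, the one of shared targets had its bound set beforehand, with a condition on the upper quartile added after its median was seen, and the test of exchanged labels and the count of splits were chosen after the result was seen. The effect of KH7 differed with and without aphidicolin for 6300 genes in the interaction test of edgeR. In a fit of these 4 groups alone 6139 genes were called. Of 100 splits of the 12 libraries, the highest apart from the real one gave 3199, and only 1 split, the real one, gave 6139 or more. The other splits mix treatments that differ by themselves, so the real one could hardly fail to give the most calls. The splits therefore do not test the interaction apart from the effects of each compound. The KH7 effect was lower with aphidicolin for GDF15 (-5.32), ATF3 (-4.09), FAM212B (-2.83), CDC6 (-2.65), DTL (-2.6), FDXR (-2.56), EPS8L2 (-2.52), TCF19 (-2.51), PIDD1 (-2.47), CCNE2 (-2.45), BBC3 (-2.41), CDKN1A (-2.34), MYBL2 (-1.91) and MKI67 (-1.12), as log2 differences. It was higher with aphidicolin for PLK1 (2.44), CDC20 (2.24), KIF20A (2.07), NRXN3 (1.92), CCNB1 (1.68), DLGAP5 (1.57), TACR1 (1.55), HMMR (1.5), AURKA (1.38) and DEPDC1 (1.34). These differences keep their sign, so lower is a smaller rise for GDF15 but a larger fall for CCNE2. Higher is a weaker fall for PLK1, which was at -3.27 with KH7 against DMSO in the authors' deposited table.

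Among the lists, the median difference was -1.29 for S phase genes, -1.30 for p53 targets, -1.12 for ATF4 targets, -0.56 for sterol genes and -0.38 for apoptosis genes, all of which were also called with an estimated correlation. The other lists called by camera were not called with an estimated correlation. They were genes of G2 and mitosis (median 0.14, adjusted p = 0.538 with an estimated correlation), trophic factors (-0.047, adjusted p = 0.12), fibroblast markers (0.50, adjusted p = 0.201) and neural progenitor markers (0.26, adjusted p = 0.282). Fatty acid synthesis (-0.27, adjusted p = 0.354), oxidative phosphorylation (0.26, adjusted p = 0.578), NRF2 targets (-0.24, adjusted p = 0.204) and NF-kB targets (-0.28, adjusted p = 0.12) were the next. SRF and MRTF targets (0.31, adjusted p = 0.23), ribosomal proteins (0.30, adjusted p = 0.598) and extracellular matrix genes (0.09, adjusted p = 0.538) completed them, and the matrix median turned to -0.04 with scaling to library size only.

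With the labels as given, many of the larger changes that aphidicolin made alone did not recur on top of KH7: of 312 genes called with a log2 change of at least 1 by aphidicolin alone in edgeR, 36.2% moved the same way from KH7 to both compounds. Shared targets of both compounds, whose second addition adds little, were argued against as the whole cause by the 53 of these genes that KH7 alone moved by under 0.5, since their median change from KH7 to both compounds, signed by the aphidicolin effect, was -0.01 (quartiles -0.265 and 0.292), where aphidicolin alone had moved them by a median of 1.19. An exchange of labels between the KH7 libraries and those with both compounds stays open. Of 7 lists called by camera at the preset correlation for aphidicolin both without and with KH7, 4 went opposite ways (S phase, p53, ATF4 and oxidative phosphorylation genes). An exchange would make them do so if the effects added up, while 3 went the same way (mitotic, interferon and matrix genes). For aphidicolin alone, camera with an estimated correlation did not call S phase (adjusted p = 0.271), oxidative phosphorylation (adjusted p = 0.577) or matrix genes (adjusted p = 0.269). Interferon genes had adjusted p = 0.597 by camera with only the members at or above the median level. By the calls at the preset correlation, the effects added up under neither labelling. Biologically, KH7 may block or reverse part of the response of these astrocytes to aphidicolin, which the label has given first, and neither this nor the order was tested.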

How the results depend on the processing

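The authors' own selection, the edgeR refit of the comparisons with DMSO, the single DMSO lanes, the RLE and library-size scalings, and limma-voom and DESeq2 for the comparisons absent from the deposited table were chosen after seeing the data. Of 5146 values of named genes under the alternatives, 5065 kept their direction and their side of the threshold, 34 no longer passed it, 42 passed it newly and 5 reversed. For the lists, 736 of 840 kept both, 75 no longer passed, 17 passed newly and 12 reversed by the direction of camera's test, which need not be that of the median. These 840 include the mean in place of the median for each of 288 pairs of list and comparison. Those values kept the reported p and could not cross the threshold, so 736 overstates how often a repeated test left the call unchanged. Counts of genes called stayed within 1.5 times the reported ones with edgeR, limma-voom, DESeq2 and every scaling tried. They were lower where fewer genes were tested or the bound was stricter, and the cause of the other changes was not tested.

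With an adjusted p under 0.01, aphidicolin against DMSO gave 3581 genes in the authors' deposited table, and its overlaps there were 2183 with KH7, 2049 with both compounds and 1365 with nocodazole. At the same bound edgeR, whose calls for aphidicolin are another set, had 988 genes called the same way for aphidicolin without and with KH7. With a log2 change of at least 1, the authors' deposited table gave 317 genes for aphidicolin, 1041 for KH7, 1292 for both compounds and 1353 for nocodazole. The authors' own selection held 1118, 2764, 3146 and 3079 genes in the same order. Among genes at or above the median level, 3339, 4843, 4670 and 4828 were called in that order. The counts among them were 4769 for both compounds against aphidicolin, 3669 in the interaction, 5196 for KH7 against nocodazole and 4452 for KH7 against aphidicolin. An estimated correlation left 6 of 14 lists called for aphidicolin, 13 of 20 for KH7, 12 of 19 for both compounds and 6 of 15 for nocodazole. It left 7 of 16 for both compounds against aphidicolin, 5 of 16 in the interaction and 10 of 20 for KH7 against aphidicolin.

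Log2 values reversed with quantile scaling for IL6 with aphidicolin (-0.04) and COL1A1 with both compounds (-0.049), and that of VIM with KH7 was 0. IL6 was also at -0.04 without DMSO replicate 2 and at 0.25 without DMSO replicate 1, the ends of its range over the libraries left out. With library-size scaling VIM with both compounds (-0.002) and GJA1 with nocodazole (-0.001) reversed. With only members at or above the median level, the direction of camera's test reversed for lists not called over all members, given here with the medians over those members. These were astrocyte identity with aphidicolin (-0.075), with KH7 (-0.052) and for KH7 against aphidicolin (0.13), and sterol genes with nocodazole (0.03). They were also interferon genes with nocodazole (0.25), in the interaction (0.45) and for KH7 against aphidicolin (0.11). For both compounds against aphidicolin they were cAMP metabolism (-0.06) and NF-kB targets (-0.19). Direction also reversed for neuron markers in the interaction (-0.34), CREB targets for KH7 against nocodazole (0.20) and A2 genes for KH7 against aphidicolin (-0.23). Neuronal markers with nocodazole kept camera's direction but lost the call, and their median went from -0.44 to 0.66.

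Leaving out each library in turn gave 5406 to 5923 genes for aphidicolin, 8060 to 8200 for KH7, 8281 to 8512 for both compounds and 8140 to 8263 for nocodazole, in edgeR fits that differ from the authors' also in the tool and the control. It gave 7878 to 8274 for both compounds against aphidicolin, 5769 to 6331 in the interaction, 9219 to 9309 for KH7 against nocodazole and 7468 to 7789 for KH7 against aphidicolin. Library numbers did not pair the libraries: 4 of 30 pairs with the same number correlated by over 0.1 across genes in their deviations from the group means (median 0.0085, other pairs 0.0155). With that number as a block, 6304 genes were called for aphidicolin, 8621 for KH7, 8809 for both compounds and 8711 for nocodazole. The blocked counts were 8441 for both compounds against aphidicolin, 6249 in the interaction, 9624 for KH7 against nocodazole and 8057 for KH7 against aphidicolin. Other pseudocounts and a fit without a filter were not run, since the unit is counts and the table was filtered before deposit, so genes with a mean under 28.7 counts were not analysed here.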

Other observations

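Of the tests in this part, those of arrest, of the share of astrocytes and of other splits were chosen after the result was seen, and those of library scaling before. Apoptosis genes were higher for 14 of 20 and lower for 4 with KH7 in the authors' deposited table (the same counts adjusted over the list alone; adjusted p = 0.000185 by camera), led by BBC3 (3.15), BIRC3 (3.06), which inhibits apoptosis, and PMAIP1 (1.62), which promotes it. With aphidicolin 11 were higher and 1 lower in the authors' deposited table (the same counts adjusted over the list alone; adjusted p = 0.0014 by camera). BBC3 and PMAIP1 also stand in the list of p53 targets, and BIRC3 in that of NF-kB targets. Genes of the unfolded protein response were higher for 15 of 24 and lower for 2 with KH7 in the authors' deposited table (the same counts adjusted over the list alone), among them the sensor ERN1 (1.98), HERPUD1 (1.48) and the transcription factor XBP1 (1.08). The unfolded protein response list had adjusted p = 0.000478 by camera and adjusted p = 0.0896 with an estimated correlation. Lysosome and autophagy genes were higher for 18 of 23 and lower for 2 with both compounds in the authors' deposited table (19 higher and 2 lower adjusted over the list alone), including the autophagy receptor SQSTM1 (1.36) and MAP1LC3B (1.2). That list had adjusted p = 0.000192 by camera and adjusted p = 0.0562 with an estimated correlation, and with KH7 alone adjusted p = 0.0101 and adjusted p = 0.164 with an estimated correlation. Heat shock genes were lower for 13 of 18 and higher for 3 with KH7 in the authors' deposited table (the same counts adjusted over the list alone), with the chaperones HSPH1 (-0.93) and HSPA8 (-0.79) lower and HSPA4L (1.27) higher. Heat shock genes had adjusted p = 0.00272 by camera and adjusted p = 0.0945 with an estimated correlation. Targets of NRF2, the regulator of the antioxidant response, were higher for 10 and lower for 5 of 18 with KH7 in the authors' deposited table (the same counts adjusted over the list alone), HMOX1 at 1.74 and NQO1 at -0.97. NRF2 targets had adjusted p = 0.0421 by camera and adjusted p = 0.373 with an estimated correlation, and adjusted p = 0.194 with only the members at or above the median level. Of 20 cell cycle inhibitors and senescence genes, 10 were higher and 9 lower with KH7 in the authors' deposited table (the same counts adjusted over the list alone), and the lamin gene LMNB1 was at -1.58. They had adjusted p = 0.0699 by camera. The 4 replication-dependent histone genes measured were too few to test, and HIST1H2AC was at 1.26 with KH7 and -1.06 with nocodazole in the authors' deposited table.

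Nuclear genes of oxidative phosphorylation were lower for 22 of 47 and higher for 1 with aphidicolin in the authors' deposited table (1 higher and 23 lower adjusted over the list alone; adjusted p = 0.00531 by camera and adjusted p = 0.577 with an estimated correlation). With KH7 27 were lower and 2 higher in the authors' deposited table (the same counts adjusted over the list alone; adjusted p = 0.0358 by camera and adjusted p = 0.677 with an estimated correlation), ATP5G1 at -0.91 and SDHA at 0.54 among them. Genes encoded in the mitochondrial genome were higher for all 13 with nocodazole in the authors' deposited table, with a median of 0.29 (the same counts adjusted over the list alone; adjusted p = 0.0972 by camera). Of 11 genes of fatty acid synthesis, 7 were higher and 3 lower with KH7 in the authors' deposited table (the same counts adjusted over the list alone; adjusted p = 0.106 by camera), the desaturase SCD at 0.92. Pan-reactive astrocyte genes were higher for 6 of 8 with both compounds in the authors' deposited table (the same counts adjusted over the list alone), SERPINA3 (2.54) and TIMP1 (0.99) among them, and lower for 2. With nocodazole 1 was higher and 6 were lower in the authors' deposited table (the same counts adjusted over the list alone). They had adjusted p = 0.0155 by camera and adjusted p = 0.135 with an estimated correlation with both compounds, and adjusted p = 0.00525 and adjusted p = 0.109 with an estimated correlation with nocodazole. With only the members at or above the median level, those with both compounds had adjusted p = 0.0818. Extracellular matrix genes were higher for 19 of 29 and lower for 1 with aphidicolin in the authors' deposited table (22 higher and 1 lower adjusted over the list alone; adjusted p = 0.00174 by camera and adjusted p = 0.269 with an estimated correlation). Genes of cAMP metabolism were higher for 14 of 29 and lower for 2 with aphidicolin in the authors' deposited table (15 higher and 2 lower adjusted over the list alone; adjusted p = 0.0297 by camera and adjusted p = 0.271 with an estimated correlation), PDE4A at 1.05 and ADCY7 at 0.74. BMP, ID and Notch genes were higher for 12 of 19 and lower for 4 with both compounds in the authors' deposited table (the same counts adjusted over the list alone; adjusted p = 0.00641 by camera and adjusted p = 0.215 with an estimated correlation), BMP2 at 1.42 and the Notch ligand JAG1 at 1.23.

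HIF targets rose with KH7. With aphidicolin 7 of 18 were higher and 0 lower in the authors' deposited table (the same counts adjusted over the list alone), and the list had adjusted p = 0.00224 by camera and adjusted p = 0.3 with an estimated correlation. Arrest of the cell cycle by any means was argued against as the whole cause, since the median of HIF targets was at most 0.116 with aphidicolin or nocodazole. This holds only if these compounds arrested the cells, which was not measured here. The choice of scaling was argued against as well, since the median with KH7 was 2.17 with scaling to library size only. That scaling put the median of all genes at -0.049, so it could move the list only little. Inhibition of soluble adenylyl cyclase, or another action of KH7 such as on mitochondrial respiration or the oxygen in the medium, may raise HIF targets, which was not tested.

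Astrocyte identity genes fell with nocodazole. A lower share of astrocytes among the cells would raise the markers of whichever cells took their place. The median of fibroblast markers was -0.793 with nocodazole, but neuronal markers at or above the median level had a median of 0.66. Bulk counts do not show which cells express these markers, so the lists cannot decide this and a lower share stays open. The choice of scaling was argued against by a median of -1.02 for the astrocyte genes with scaling to library size only. That scaling put the median of all genes at -0.10, so it could move the list only little. Arrest by any means was argued against as the whole cause by the median with aphidicolin, 0.07 in the authors' deposited table (quartiles -0.20 and 0.45) against -0.87 with nocodazole, but not by that with KH7, -0.146 (quartiles -0.79 and 0.37), whose members went both ways, with GFAP (-1.49) and S100B (-0.97) lower, and GFAP at -1.99 with both compounds. Whether aphidicolin, KH7 or nocodazole arrested the cells was not measured here. Arrest as part of the cause, a loss of microtubules, or a hold in mitosis may lower astrocyte identity genes, which was not tested.

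Splits of the libraries of each pair of groups number 10, of which 1, the real one, gave as many calls in each comparison, too few for a share under 0.05. In edgeR fits of 2 groups the real counts were 6343 for aphidicolin, 8950 for KH7, 8814 for both compounds and 9166 for nocodazole against DMSO. They were 7926 for both compounds against aphidicolin, 9773 for KH7 against nocodazole and 7841 for KH7 against aphidicolin. The highest count of another split was 0 in each, with at most 338 genes at an unadjusted p under 0.05 in edgeR.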
